A study of Mus musculus with 6 samples.

How the data were processed

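The series holds gene expression arrays of total liver RNA from 6 mice labelled as Ppara knockouts on a C57 background, 3 injected with an adenoviral TFEB vector and 3 not injected. The groups and replicate numbers come from the labels, which call the arrays biological replicates. Per the labels' protocols, RNA was purified with column kits and biotin-labelled cRNA was made with an Affymetrix in vitro transcription kit. Per the submitters' processing notes, the authors used RMA in the affy package, which corrects background, sets the arrays to one distribution by quantile normalization and summarises probes per probe set; versions are not given in the sources used here. The deposited values are log2 expression levels, between 3.08 and 15.20, with array medians from 6.92 to 6.93. Quantile normalization makes overall shifts in RNA content invisible, and RMA compresses changes at low levels, so folds of dim genes can be understated.

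The table held 22690 probe sets, 64 of them controls. In the platform annotation 20393 probe sets had 1 gene symbol, 691 had several and 1606 had none (controls included), and only those with 1 symbol were named. The gene IDs of 20364 of them were in the reference gene table, and 0 symbols needed updating. After controls were removed, 20380 probe sets for 12393 genes were tested, with 1 probe set per gene, that with the highest mean over all arrays; 4956 genes had more than 1. Probe sets ending in _s_at or _x_at can detect related genes, so values of families such as Saa, Acot and Gst are uncertain in that respect. Of 105 genes named by rule, 41 had several probe sets, and in 6 a further probe set had the opposite sign, none of these past the threshold.

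The comparison was fitted with limma (version 3.58.1, R 4.3.3; lmFit and eBayes) on the deposited log2 values, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. All changes are injected minus not-injected. Levels are given as mean ± SD of 3 arrays and log2 changes as estimate ± SE; "rose" and "fell" are used of genes with an adjusted p under 0.05. The test was checked on simulated data with 200 of 12393 genes changed. At a log2 change of 0.5 it recovered 71% of them with 13 unchanged genes called. At 1 it recovered 95.5% with 8, and with no change it called 0. The simulated genes varied independently and with the same spread in both groups. In the data the injected arrays varied more (median SD ratio 1.27 over all genes), so these rates may not hold there.

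Before the data were examined, 37 gene lists were fixed, covering lysosome, autophagy, lipid, bile acid, glucose, mitochondrial, stress, immune, sex-biased, zonation and cell type genes. Lists with at least 5 measured members (36) were tested by camera with a preset correlation of 0.01, adjusted over the lists, and with an estimated correlation. With an estimated correlation, camera also takes its degrees of freedom from the few arrays and not from the genes, which makes it stricter. A single simulated data set without change gave 0 called lists. Its genes varied independently, so it does not show how often correlated lists are called without a change. The rule for named genes was fixed at the same time. It took Tfeb and Ppara, the 10 largest rises and 10 largest falls among called genes whose groups did not overlap, and of each list the 2 called members with the smallest p in each direction, or the 1 with the smallest p where none passed. Gpnmb, which completes a count of 3, and the genes marked as such in the text were named after their values were seen.

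Alternatives fixed in advance were the mean of a gene's probe sets, leaving out _x_at and _s_at probe sets, median centring, cyclic loess, leaving out genes below the median level, an intensity trend with a robust prior, array weights, the replicate number as a block, leaving out each array, an unmoderated test, other thresholds, every probe set, and fry. One was added later, taking the spread from the 3 injected arrays alone. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.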

Results

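Liver RNA was profiled from 6 mice labelled as lacking Ppara, the gene of a nuclear receptor that switches on fatty acid oxidation genes in liver. Per the labels, 3 of the mice had received an adenoviral vector for TFEB, a transcription factor known for activating lysosomal and autophagy genes; the other 3 mice were not injected. All mice were 1 month old, and each array is 1 mouse. The comparison asks which liver transcripts differ between the injected and the not-injected group. Array-to-array correlations across the tested genes, with 1 probe set per gene, were 0.998 to 0.999 within the not-injected group. They were 0.995 to 0.998 within the injected group and 0.989 to 0.993 between groups. The small number of arrays limits the precision.

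The targeted genes come first. The Tfeb probe set gave 7.55 ± 0.07 (SD, n = 3) in not-injected and 7.59 ± 0.12 in injected livers, a log2 change of 0.04 ± 0.07 (SE; adjusted p = 0.777). The Ppara probe set gave 8.95 ± 0.07 and 9.08 ± 0.04 (log2 change 0.13 ± 0.05; adjusted p = 0.149). The labels say neither which species' TFEB the vector carries nor which part of Ppara is missing, so neither probe set checks the labels.

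Vnn1, a pantetheinase gene and classical PPAR-alpha target, showed the largest rise, from 5.78 ± 0.20 to 10.79 ± 0.19 (SD, n = 3), or 32.2-fold (log2 change 5.01 ± 0.13 SE; adjusted p = 4.10e-06). Gpx3, for a secreted glutathione peroxidase, rose 28.1-fold (4.81 ± 0.19). Cyp4a14, for a fatty acid hydroxylase, rose 19.4-fold (4.27 ± 0.20), and Cyp46a1, for cholesterol 24-hydroxylase, 14.7-fold (3.88 ± 0.14). Cox7a1 (3.50 ± 0.17) and Cox8b (3.30 ± 0.27), which encode cytochrome oxidase subunits typical of muscle and brown fat, rose 11.3-fold and 9.83-fold. Bex2 (3.43 ± 0.32), the stress-responsive Nupr1 (3.34 ± 0.35) and Plet1 (2.83 ± 0.06) rose too; a second Plet1 probe set gave -0.15. The remaining gene among the 10 largest rises was Saa2, for an acute phase protein, at 3.32 ± 0.91 with injected arrays at 9.97, 13.37 and 13.95. Its adjusted p of 0.0450 rose to as much as 0.144 and the call was lost without not-injected replicate 1, 2 or 3 or TFEB-injected replicate 2 or 3.

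The largest fall was in Gadd45g, a growth arrest gene, from 9.94 ± 0.02 to 7.38 ± 0.39 (SD, n = 3), or 5.91-fold lower (log2 change -2.56 ± 0.17 SE; adjusted p = 1.66e-04). Rnase2a (-2.23 ± 0.10), the organic anion transporter gene Slc22a7 (-2.01 ± 0.25), the water channel gene Aqp4 (-1.90 ± 0.09), Tiam2 (-1.89 ± 0.18) and Moxd1 (-1.84 ± 0.09) followed. Onecut1, for a hepatocyte transcription factor, fell by 1.76 ± 0.05 on the log2 scale. Hsd3b2 (-1.60 ± 0.11), the aldehyde oxidase gene Aox3 (-1.53 ± 0.11) and Dusp1 (-1.49 ± 0.13), for a MAP kinase phosphatase, completed the 10 largest falls.

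**Figure D1:**
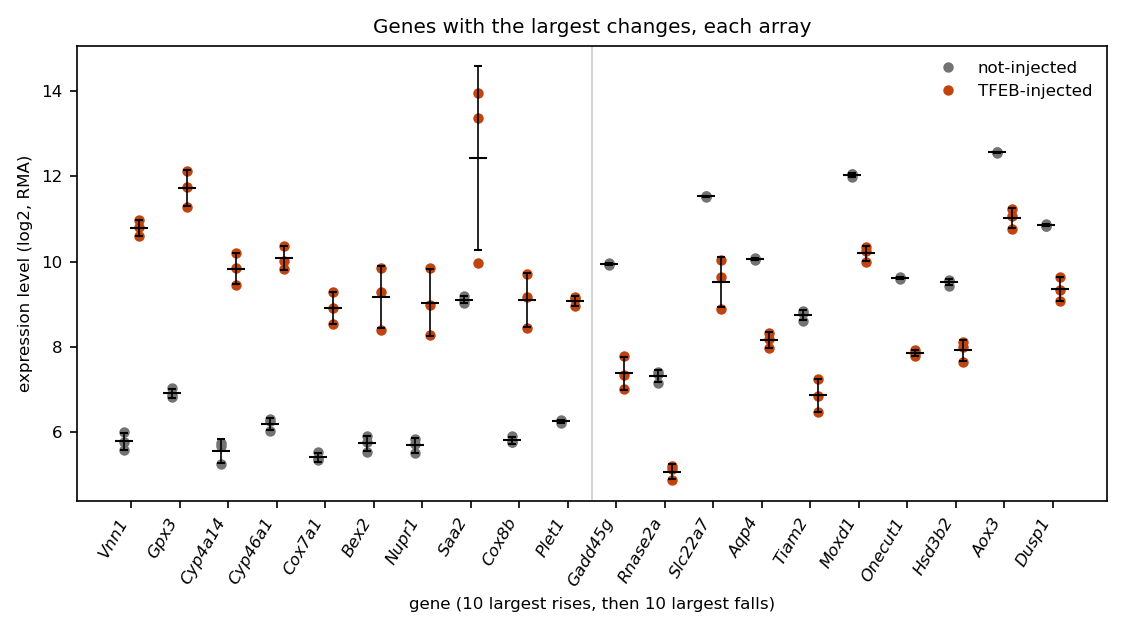
Expression level (log2, RMA) of the 10 genes with the largest rises and the 10 with the largest falls, one point per array, with group mean and SD (n = 3 not-injected, n = 3 TFEB-injected). Saa2 has the widest spread of the 20 genes, with injected arrays from 9.97 to 13.95.

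Genes of the lysosome, the acidic compartment that breaks down macromolecules, shifted upward as a list. Of 34 measured genes for lysosomal enzymes and membrane proteins, 22 rose and 0 fell (24 and 0 adjusted over the list alone), with a median log2 change of 0.34. The cathepsin A gene Ctsa rose from 9.82 ± 0.03 to 11.20 ± 0.20 (SD, n = 3; log2 change 1.38 ± 0.10 SE), and the peptidase gene Tpp1 rose by 0.89 ± 0.06. Neu1 (1.40 ± 0.16) and Hexa (1.29 ± 0.10), named after their values were seen, lay in the same range. Of 15 subunit genes of the V-ATPase, the proton pump that acidifies lysosomes, 13 rose and 0 fell (13 and 1 adjusted over the list alone), among them Atp6v1d (0.57 ± 0.05) and Atp6v1a (0.70 ± 0.06); the median was 0.41. Both lists shifted upward against the other genes (camera, adjusted p = 7.14e-12 and 5.60e-09), but not with an estimated correlation (adjusted p = 0.219 and 0.0942). Markers of macrophages, which are rich in lysosomes, were also higher, with a median of 0.44.

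Among 7 MiT/TFE family members and nutrient-sensing targets, 3 rose and 0 fell (6 and 0 adjusted over the list alone), with a median of 0.35. Ppargc1a, for a coactivator of mitochondrial biogenesis, rose 4.77-fold (2.25 ± 0.32), and Rragc, for a GTPase of the mTORC1 pathway, rose by 0.73 ± 0.07. Gpnmb, the other gene that passed, changed by 1.98 ± 0.30. The list shifted upward (camera, adjusted p = 1.71e-04; adjusted p = 0.0942 with an estimated correlation), and 5 members passed without TFEB-injected replicate 3. Autophagy genes went both ways, with 5 of 26 higher and 2 lower (5 and 3 adjusted over the list alone). The list did not shift against the other genes (median 0.00, camera, adjusted p = 0.427). Fry, which tests a list against no change, gave an adjusted p of 0.00205. Gabarapl1 (1.18 ± 0.04) and Map1lc3b (0.42 ± 0.05), both for autophagosome membrane proteins, rose; 1 of the other 3 Map1lc3b probe sets gave -0.06. Atg16l1 fell (-0.29 ± 0.05), as did Atg5 (-0.18 ± 0.05), whose call was lost without any 1 of the 6 arrays (adjusted p up to 0.145). Only 4 autophagy genes passed without not-injected replicate 1 or 2 or TFEB-injected replicate 2.

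Lists of mitochondrial genes for fatty acid oxidation and respiration shifted upward by camera, but not with an estimated correlation. Of 18 genes for mitochondrial fatty acid oxidation and ketogenesis, 12 rose and 0 fell (14 and 1 adjusted over the list alone), with a median of 0.27. They included Slc25a20, for the carnitine-acylcarnitine carrier (0.57 ± 0.05), and Acadl, for long-chain acyl-CoA dehydrogenase (0.69 ± 0.08). Of 30 oxidative phosphorylation genes, 22 rose and 0 fell (25 and 0 adjusted over the list alone), with a median of 0.21; the complex I gene Ndufs1 rose by 0.50 ± 0.05 and the cytochrome c gene Cycs by 0.38 ± 0.04. The camera adjusted p was 3.15e-07 for fatty acid oxidation and 2.98e-12 for oxidative phosphorylation. Neither call held with an estimated correlation (adjusted p = 0.0942 and 0.247). The oxidative phosphorylation count was 11, 11 and 14 without not-injected replicates 1, 2 and 3 and 10 without TFEB-injected replicate 2.

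PPAR-alpha target genes outside fatty acid oxidation shifted upward as a list in the injected livers, from mice labelled as lacking Ppara. Of 17 measured, 11 rose and 0 fell (12 and 1 adjusted over the list alone), with a median of 0.35 (camera, adjusted p = 1.81e-06; adjusted p = 0.0942 with an estimated correlation). Besides Vnn1, the lipid droplet gene Plin2 rose by 0.80 ± 0.05; the fatty acid transporter gene Cd36 (2.01 ± 0.14) and the pyruvate dehydrogenase kinase gene Pdk4 (1.38 ± 0.30) were named after their values were seen. The Pdk4 call was lost without not-injected replicate 1, 2 or 3 or TFEB-injected replicate 2 (adjusted p up to 0.0750). The count was 7 without not-injected replicate 2 and 7 without TFEB-injected replicate 2. Peroxisomal and microsomal fatty acid oxidation genes were mixed, with 4 of 17 higher and 3 lower (8 and 4 adjusted over the list alone; median 0.15; adjusted p = 0.0919). Besides Cyp4a14, the thiolase gene Acaa1b rose (0.50 ± 0.04), while Acot3 (-0.48 ± 0.08) and the transporter gene Abcd3 (-0.31 ± 0.06) fell. Without TFEB-injected replicate 1 this list shifted upward (adjusted p = 0.0471).

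**Figure D2:**
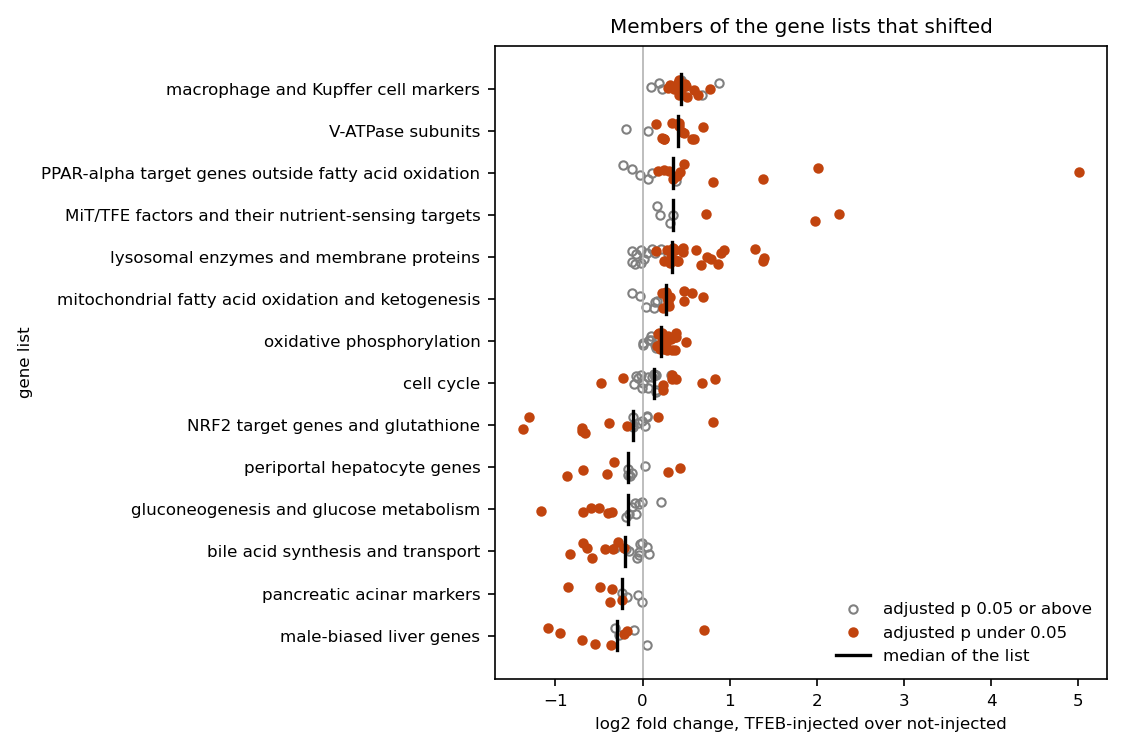
Log2 fold change (TFEB-injected over not-injected) of each member of the 14 gene lists that shifted by camera, one point per gene, filled where the adjusted p was under 0.05, with the list median as a bar. The macrophage list has the highest median (0.44) and the male-biased list the lowest (-0.29).

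Lipid synthesis genes went both ways. Of 21 genes for fatty acid and triglyceride synthesis, 5 rose and 7 fell (5 and 9 adjusted over the list alone). The median was -0.09, with no list shift against the other genes (camera, adjusted p = 0.413), while fry gave an adjusted p of 0.0199. The ATP citrate lyase gene Acly (-0.70 ± 0.04) and the malic enzyme gene Me1 (-0.70 ± 0.06) fell, whereas the desaturase gene Fads2 (0.69 ± 0.04) and Acacb (1.05 ± 0.07), for a mitochondrial acetyl-CoA carboxylase, rose. Of 19 cholesterol synthesis genes, 2 rose and 2 fell (2 and 2 adjusted over the list alone), with a median of -0.05, a mean of 0.02 and no shift (adjusted p = 0.922). Fdps, for farnesyl diphosphate synthase, rose by 1.06 ± 0.08. The other 3 calls, Msmo1 (0.28 ± 0.08), Fdft1 (-0.32 ± 0.06) and Idi1 (-0.23 ± 0.06), were each lost without not-injected replicate 2 or TFEB-injected replicate 2 (adjusted p up to 0.150, 0.0629 and 0.140). Msmo1 and Idi1 were also lost without not-injected replicate 1 or 3 or TFEB-injected replicate 3, and another Fdft1 probe set gave 0.07. The count of 4 fell to 2, 1 and 2 without not-injected replicates 1, 2 and 3 and to 1 and 2 without TFEB-injected replicates 2 and 3.

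Some genes of bile acid handling and gluconeogenesis fell. Of 18 bile acid genes, 8 fell and 0 rose (9 and 0 adjusted over the list alone), with a median of -0.20 (camera, adjusted p = 4.57e-04; adjusted p = 0.214 with an estimated correlation). The sterol exporter gene Abcg8 (-0.58 ± 0.05) and the reductase gene Akr1d1 (-0.64 ± 0.06) were examples; Cyp7a1, the rate-limiting enzyme of bile acid synthesis, named after its value was seen, fell by 0.83 ± 0.15. Of 14 gluconeogenesis and glucose metabolism genes, 6 fell and 0 rose (7 and 1 adjusted over the list alone), with a median of -0.17 (camera, adjusted p = 2.81e-04; adjusted p = 0.0942 with an estimated correlation). Pck1, for phosphoenolpyruvate carboxykinase, went from 13.20 ± 0.04 to 12.51 ± 0.02 (SD, n = 3; log2 change -0.68 ± 0.05 SE), and Tat, for tyrosine aminotransferase, fell by 0.49 ± 0.05.

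Several detoxification genes fell. Of 17 NRF2 target and glutathione genes, 7 fell and 2 rose (7 and 2 adjusted over the list alone), with a median of -0.11 (camera, adjusted p = 0.0190; adjusted p = 0.389 with an estimated correlation). The glutathione S-transferase gene Gsta2 fell by 1.37 ± 0.11, as did Me1, whereas the heme oxygenase gene Hmox1 rose by 0.81 ± 0.07. Ugdh rose by 0.18 ± 0.04, a call lost without any 1 of the arrays but TFEB-injected replicate 3 (adjusted p up to 0.134). Of 19 xenobiotic genes, 5 fell and 2 rose (7 and 2 adjusted over the list alone). The median was -0.12, with no shift against the other genes (camera, adjusted p = 0.125), while fry gave an adjusted p of 0.0077. Cyp3a25 (-0.43 ± 0.07) and Cyp2c55 (-0.55 ± 0.09) fell, and the sulfotransferase gene Sult5a1 rose (0.84 ± 0.06). Cyp2b10 rose by 1.57 ± 0.41, a call lost without not-injected replicate 1, 2 or 3 or TFEB-injected replicate 2 (adjusted p up to 0.114). The xenobiotic count of 7 was 3 without each of those 4 arrays.

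Liver genes with male-biased expression fell in 7 of 12 cases and rose in 1 (8 and 1 adjusted over the list alone), with a median of -0.29 (camera, adjusted p = 5.23e-04; adjusted p = 0.477 with an estimated correlation). The median shift was -0.13, -0.23 and -0.55 in TFEB-injected replicates 1, 2 and 3. The elongase gene Elovl3 fell by 0.95 ± 0.05 and Susd4 by 0.69 ± 0.08. Cyp4a12a rose (0.71 ± 0.15), a call lost without not-injected replicate 1 or 2 or TFEB-injected replicate 2 (adjusted p up to 0.0647). The count of 8 was 4, 4 and 5 without not-injected replicates 1, 2 and 3 and 4 without TFEB-injected replicate 2. Among 13 female-biased genes, Cyp4a14 rose, Cyp17a1 (-1.23 ± 0.06) and Acot3 fell (1 and 2 adjusted over the list alone), and the list did not shift (median -0.01, mean 0.19, camera direction down; adjusted p = 0.600). Of 4 measured Y-linked genes and Xist, Kdm5d was the 1 that fell (-0.27 ± 0.04; 0 and 1 adjusted over the list alone), while another of its probe sets gave 0.03.

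Periportal hepatocyte genes fell in 4 of 11 cases and rose in 2 (5 and 2 adjusted over the list alone; median -0.16; camera, adjusted p = 0.0376; adjusted p = 0.247 with an estimated correlation). The histidase gene Hal (-0.87 ± 0.05) and Pck1 fell, whereas Pigr (0.43 ± 0.05) and Ctsc (0.29 ± 0.05) rose. The list call was lost without not-injected replicate 3 (adjusted p = 0.0828) or TFEB-injected replicate 3 (adjusted p = 0.0795), after median centring of the arrays (adjusted p = 0.0675), with the mean of a gene's probe sets (adjusted p = 0.0769) and with genes below the median level left out (adjusted p = 0.132). Of 15 pericentral genes, 3 fell and 1 rose (7 and 1 adjusted over the list alone; median -0.16; adjusted p = 0.137). Lect2 fell by 0.64 ± 0.04 and the glutamate transporter gene Slc1a2 rose by 0.50 ± 0.05; Slc1a4 (-0.25 ± 0.06) lost its call without not-injected replicate 1 or 3 or TFEB-injected replicate 1 or 2 (adjusted p up to 0.102). The pericentral count of 4 was 2 without not-injected replicate 1 or 3 or TFEB-injected replicate 2.

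Macrophage and Kupffer cell markers were higher in the injected livers. Of 19 markers, 13 rose and 0 fell (17 and 0 adjusted over the list alone), with a median of 0.44, or 1.36-fold (camera, adjusted p = 2.21e-10; adjusted p = 0.219 with an estimated correlation). Cd5l rose from 10.91 ± 0.03 to 11.55 ± 0.04 (SD, n = 3; log2 change 0.63 ± 0.05 SE) and the complement receptor gene Vsig4 rose by 0.50 ± 0.06. The median shift of the list was 0.57, 0.51 and 0.28 in TFEB-injected replicates 1, 2 and 3. Among 15 endothelial markers, the scavenger receptor gene Stab2 (1.42 ± 0.05) and the hyaluronan receptor gene Lyve1 (0.89 ± 0.07) rose and 0 fell (2 and 0 adjusted over the list alone), while the list did not shift (median -0.02, mean 0.13; adjusted p = 0.600).

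**Figure D3:**
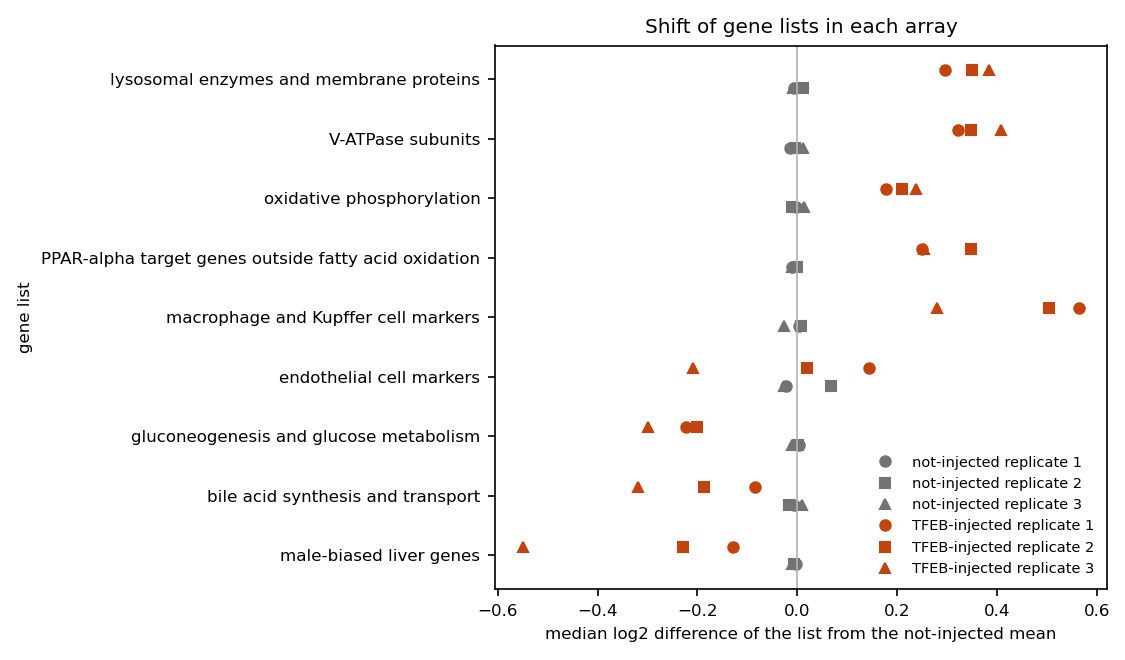
Median log2 difference of 9 gene lists from the not-injected mean, one marker per array (n = 3 not-injected, n = 3 TFEB-injected; marker shape gives the replicate number). The lysosomal list sits between 0.30 and 0.38 in the injected arrays, the macrophage list between 0.28 and 0.57, with replicate 3 highest in the first and lowest in the second, and the endothelial list between -0.21 and 0.14.

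Pancreatic acinar markers, at low levels in most cases, fell in 5 of 9 cases and rose in 0 (5 and 0 adjusted over the list alone), with a median of -0.24 (camera, adjusted p = 0.00145; adjusted p = 0.280 with an estimated correlation). The elastase gene Cela1 fell from 10.62 ± 0.04 to 9.77 ± 0.07 (SD, n = 3; log2 change -0.85 ± 0.05 SE) and the trypsinogen gene Prss2 by 0.38 ± 0.07. The count of 5 was 3, 2 and 3 without not-injected replicates 1, 2 and 3 and 2 and 3 without TFEB-injected replicates 1 and 2. Other cell type lists did not shift: T and NK cell (16 markers), B and plasma cell (8), neutrophil (10), stellate cell and fibroblast (15), cholangiocyte (10), erythroid (6), adipocyte and muscle (10) and secreted liver proteins (13) had camera adjusted p of 0.913, 0.734, 0.922, 0.922, 0.0919, 0.267, 0.396 and 0.396. Their medians were -0.01, -0.05, 0.02, -0.01, -0.09, -0.11, -0.04 and -0.03, with the mean on the other side of 0 for T and NK cells (0.01) and stellate cells (0.00). The heme synthesis gene Alas2 (-0.81 ± 0.07) and Sox9 (-0.33 ± 0.05) fell and Col3a1 (0.32 ± 0.05) rose. Calls for Vim (0.29 ± 0.05), Lrat (-0.48 ± 0.10), Reln (-0.19 ± 0.04), Ighm (-0.99 ± 0.20), Gzma (0.36 ± 0.08), S100a8 (0.25 ± 0.07) and Ambp (-0.20 ± 0.04) were each lost without TFEB-injected replicate 2, and all but that of Vim also without at least 1 not-injected array. The highest adjusted p with an array left out was 0.0511, 0.0580, 0.101, 0.0632, 0.0700, 0.154 and 0.0739 in that order. Of the 11 Ighm probe sets, 3 had the opposite sign (0.10, 0.03 and 0.13), none of these past the threshold. The stellate count of 5 was 3, 3 and 2 without not-injected replicates 1, 2 and 3 and 1 without TFEB-injected replicate 2, and the B cell and cholangiocyte counts of 1 were 2 without TFEB-injected replicate 1. Of 10 adipocyte and muscle markers 0 passed; Mylpf had the smallest p (-0.12 ± 0.06; adjusted p = 0.228). Adjusted over the list alone, the counts of higher and lower genes were 1 and 0 for T and NK cells, 1 and 2 for B cells, 0 and 0 for neutrophils, 3 and 2 for stellate cells, 0 and 2 for cholangiocytes, 0 and 1 for erythroid markers, 0 and 0 for adipocyte and muscle markers and 0 and 1 for secreted proteins.

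Interferon response genes did not rise as a group after adenoviral injection: 2 of 27 rose and 9 fell (4 and 9 adjusted over the list alone), with a median of -0.10 and no list shift (camera, adjusted p = 0.125). The antiviral genes Oasl1 (-0.94 ± 0.12) and Ifih1 (-0.44 ± 0.05) fell, and the ISG15 protease gene Usp18 rose (0.74 ± 0.05). Psmb9 rose (0.26 ± 0.07), a call lost without not-injected replicate 1, 2 or 3 or TFEB-injected replicate 2 or 3 (adjusted p up to 0.122). The count of 11 was 5, 4 and 5 without not-injected replicates 1, 2 and 3 and 7 without TFEB-injected replicate 2, and the list shifted downward without TFEB-injected replicate 1 (adjusted p = 0.0182). Of 23 acute phase genes, 6 rose and 4 fell (8 and 4 adjusted over the list alone; median 0.10; adjusted p = 0.284). The pentraxin gene Apcs rose (0.97 ± 0.17), while Cebpd (-0.83 ± 0.06) and Steap4 (-0.86 ± 0.07) fell; Saa3 (0.61 ± 0.13) lost its call without not-injected replicate 1 or 2 or TFEB-injected replicate 2 (adjusted p up to 0.0754). The acute phase count of 10 was 4, 4 and 5 without not-injected replicates 1, 2 and 3 and 4 without TFEB-injected replicate 2, and the list shifted upward without TFEB-injected replicate 1 (adjusted p = 0.00206).

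Cell cycle genes were higher in 7 of 25 cases and lower in 2 (7 and 2 adjusted over the list alone), with a median of 0.13 (camera, adjusted p = 0.0264; adjusted p = 0.477 with an estimated correlation). The microtubule regulator gene Stmn1 rose (0.68 ± 0.10) and Rrm2, for a ribonucleotide reductase subunit, fell (-0.47 ± 0.07). The list call was lost without TFEB-injected replicate 3 (adjusted p = 0.0949) and with genes below the median level left out (adjusted p = 0.561). A test of the list against no change, fry, gave an adjusted p of 0.118. Ccne2 (0.23 ± 0.05) lost its call without not-injected replicate 2 or TFEB-injected replicate 2 and Cdc20 (-0.23 ± 0.04) without TFEB-injected replicate 2 (adjusted p up to 0.0686 and 0.0551); both other Cdc20 probe sets gave positive values, 0.13 and 0.33. The count of 9 was 4, 3 and 4 without not-injected replicates 1, 2 and 3 and 2 without TFEB-injected replicate 2. Of 12 p53 target genes, 4 rose and 0 fell (4 and 0 adjusted over the list alone; median 0.06; adjusted p = 0.112), among them Plk2 (0.81 ± 0.06) and Btg2 (0.41 ± 0.07). Of 22 ER stress genes, Ddit3 (0.37 ± 0.06) and Herpud1 (0.37 ± 0.08) rose and 0 fell (2 and 0 adjusted over the list alone; median 0.01; adjusted p = 0.913); the Herpud1 call was lost without not-injected replicate 1 or 2 or TFEB-injected replicate 2 (adjusted p up to 0.0695). That count was 1, 1 and 1 without not-injected replicates 1 and 2 and TFEB-injected replicate 2, and 4 and 8 without TFEB-injected replicates 1 and 3. Of 17 circadian clock genes 0 passed (0 adjusted over the list alone; median -0.03; adjusted p = 0.922); Cry1 had the smallest p (0.25 ± 0.09; adjusted p = 0.0970), and 1 and 4 clock genes passed without TFEB-injected replicates 1 and 3. Of 11 fetal liver genes, Igdcc4 was the 1 that fell (-0.20 ± 0.05; 0 adjusted over the list alone; median -0.03; adjusted p = 0.922), a call kept only without TFEB-injected replicate 1 (adjusted p up to 0.104).

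Over all 12393 genes, 2219 (17.9%) passed an adjusted p of 0.05 by limma, with 1238 higher and 981 lower, or 55.8% higher. After median centring of the arrays the split was 1060 higher and 1352 lower, or 43.9% higher. At least a 2-fold change was seen in 100 higher and 28 lower genes, and in 4601 genes (37.1%, against 10% by chance) the injected arrays did not overlap the not-injected arrays. The count was 1271, 1345 and 1448 without not-injected replicates 1, 2 and 3 and 1229 without TFEB-injected replicate 2. Of 36 lists tested by camera, 14 shifted, 8 upward and 6 downward. None of them passed with an estimated correlation, where the lowest adjusted p was 0.0942 and 8 lists had an unadjusted p under 0.05. The estimate was below the preset 0.01 for the PPAR-alpha target (-0.03), MiT/TFE (-0.08), gluconeogenesis (-0.06) and periportal (-0.06) lists. Their loss of the call therefore did not come from a higher correlation. The controls received no vector, so effects of injection, of adenovirus and of TFEB cannot be separated. The labels do not say whether the arrays were processed in batches, so a difference in array processing between the groups cannot be separated from these either. Probe sets for bacterial control transcripts, commonly added to RNA or to the hybridisation mix, were also lower in the injected arrays: all 24 dap, lys, phe and thr probe sets had a lower mean (median difference -0.44), as did all 18 bio and cre probe sets (-0.16), and every change is relative to the overall signal of the array.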

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

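The spread taken from the injected arrays alone was chosen after the data were seen; the other settings were planned. The count of 2219 genes was 5854 with array weights, whose estimation stopped before full convergence, and 1039 with the spread of the 3 injected arrays alone. It was 3560 by an unmoderated test at an unadjusted p under 0.05 (1486 adjusted), 128 with a log2 change of at least 1 required, and between 1229 and 2409 with 1 array left out, where fewer samples were fitted. With every named probe set it was 3132, at an adjusted p under 0.1 it was 3089, and the mean of probe sets, no _x_at or _s_at probe sets, median centring, cyclic loess, no dim genes, and an intensity trend gave 2111 to 2513. With the replicate number as a block, 1533 genes and 14 lists passed. Same-numbered arrays deviated with correlations of 0.01, -0.13 and -0.11, which gave no sign of pairing. The labels state no pairing, and so few arrays per group cannot exclude one. Of the lists, 14 shifted; the count was 0 with an estimated correlation, 12 to 17 with 1 array left out, and 10 without dim genes. Fry, which tests each list against no change and not against other genes, called 21, among them 13 of the 14. The other lists it called were autophagy (adjusted p = 0.00205), peroxisomal and microsomal fatty acid oxidation (0.00271), p53 targets (0.00271) and xenobiotic genes (0.0077). Fatty acid and triglyceride synthesis (0.0199), pericentral (0.0452), cholangiocyte (0.0185) and erythroid (0.0255) genes were called as well. Called members over all lists numbered 227, against 379 with array weights, 126 with the injected spread, and 143 to 236 with 1 array left out. Cdc20 changed sign, to 0.079 with the mean of its probe sets and to 0.13 without _x_at or _s_at probe sets. Apart from these, the settings of the named genes gave 1426 values on the same side of the threshold, 131 no longer past it and 3 newly past it. Tfeb, not past the threshold in the main setting (0.04), was at -0.09 with array weights and -0.01 without TFEB-injected replicate 3, also not past it. Causes not shown by a setting's own construction were not tested. Signal near background limits what can be seen of dim genes.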

Other observations

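The gene families here, the comparisons with macrophage, endothelial and PPAR-gamma-linked genes and the split of the control probe sets are tests chosen after the results were seen. Tricarboxylic acid cycle genes shifted upward, with 11 of 13 higher and 0 lower and a median log2 change of 0.37 (camera, adjusted p = 1.58e-08; adjusted p = 0.180 with an estimated correlation). Idh2, for mitochondrial isocitrate dehydrogenase, rose by 1.43 ± 0.08 (SE, n = 3) and Ogdh by 0.72 ± 0.06. Of 71 mitochondrial ribosomal protein genes 19 rose and 1 fell (median 0.08; camera, adjusted p = 3.86e-05; 0.274 with an estimated correlation). Of 21 mitochondrial import genes 6 rose and 0 fell (median 0.12; camera, adjusted p = 0.00134; 0.180 with an estimated correlation). Among 9 mitochondrial isoforms typical of muscle and brown fat, Slc25a4 (2.15 ± 0.23), Cox7a1 and Cox8b were the 3 that rose, and 0 fell. This family did not shift (median -0.06, camera, adjusted p = 0.27). Cox7a1 and Cox8b were already known as large rises when it was chosen. Of 19 lysosomal genes outside the fixed list, 10 rose and 0 fell (median 0.23; camera, adjusted p = 7.37e-05; 0.180 with an estimated correlation), including the peptidase gene Dpp7 (1.98 ± 0.12) and the cathepsin gene Ctsz (1.21 ± 0.07).

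Glutathione S-transferase genes went the other way, with 11 of 18 lower and 1 higher and a median of -0.32 (camera, adjusted p = 8.92e-06; adjusted p = 0.180 with an estimated correlation). Gsta4 fell by 1.31 ± 0.13 and Gstm2 by 0.69 ± 0.08, while Gsto1 rose by 0.33 ± 0.05; probe sets of this family can detect several members. Of 9 UDP-glycosyltransferase genes 3 fell and 0 rose (median -0.18; camera, adjusted p = 0.00398; adjusted p = 0.371 with an estimated correlation). Those that fell were Ugt3a1 (-0.52 ± 0.05), Ugt3a2 (-0.22 ± 0.05) and Ugt2b5 (-0.25 ± 0.06). Cytosolic ribosomal proteins (1 higher and 1 lower of 47), proteasome subunits (3 and 2 of 38), peroxins (0 and 1 of 12) and serpins (4 and 6 of 30) did not shift, with camera adjusted p of 0.227, 0.873, 0.410 and 0.291. The medians of the families that shifted kept their sign after median centring and after cyclic loess, but that of mitochondrial ribosomal proteins went from 0.08 to 0.048 and 0.060.

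Of the 10 splits of the 6 arrays into 3 and 3, 1 gave as many genes as the real one, which is the real split itself with 2219, and the highest of the others gave 0. With 10 splits no share under 0.05 can be reached.

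Macrophage markers and lysosomal genes shifted upward as lists (13 of 19 and 22 of 34 rose; adjusted p = 0.219 for both with an estimated correlation), so more macrophage RNA is a candidate source of the lysosomal shift. Of the 35 called lysosomal and V-ATPase genes 17 lay above the marker median of 0.44, so a macrophage source and a change in hepatocytes cannot be told apart. Ctsa, Hexa, Neu1 and, narrowly, Tpp1 (0.89) also lay above the marker with the largest change, Marco (0.87 ± 0.31, adjusted p = 0.0991). Marco, however, reached 1.27 without TFEB-injected replicate 3, where Ctsa was at 1.27. In TFEB-injected replicates 1, 2 and 3 the median shift was 0.57, 0.51 and 0.28 for macrophage markers, 0.30, 0.35 and 0.38 for lysosomal genes and 0.32, 0.35 and 0.41 for V-ATPase genes, opposite orders in too few arrays for a test. A lower hepatocyte share as the full source was argued against by the endothelial median of -0.016. It lay below the macrophage median by more than the standard errors over members (0.11 endothelial, 0.05 macrophage). Those errors treat members as independent, although the estimated correlation was 0.34 among endothelial markers. The endothelial markers Stab2 (1.42) and Lyve1 (0.89) rose by more than the macrophage median. The endothelial median shift was 0.14, 0.02 and -0.21 in TFEB-injected replicates 1, 2 and 3. That is the order of the macrophage markers, in too few arrays for a test. Macrophage number or state, a partial change in hepatocyte share, vector and TFEB stay open.

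The list of PPAR-alpha target genes shifted upward in mice labelled as lacking Ppara (11 of 17 rose, 7 without not-injected or TFEB-injected replicate 2; adjusted p = 0.0942 with an estimated correlation). The list median of 0.35 was 0.32 after median centring, which moved every gene by -0.031, and 0.34 after cyclic loess. Both ran on values already quantile-normalized, so they do not test the authors' normalization. Random lists matched on mean level had medians between -0.09 and 0.08 in 95% of draws. The list therefore rose relative to genes of like level. Quantile normalization itself holds such random lists near 0, so they cannot decide whether the authors' normalization contributed. A higher Pparg level is a candidate explanation, because Pparg rose by 0.86 ± 0.21 (SE; 95% interval 0.36 to 1.35), with all 3 injected arrays above the not-injected ones. Of genes linked to PPAR-gamma, chosen after the result, Plin4 (1.88 ± 0.24) and Mogat2 (1.75 ± 0.21) rose, Mogat1 fell (-0.21 ± 0.05; adjusted p = 0.0346) and Fabp4 was at -0.11 ± 0.11 (adjusted p = 0.581). The Pparg call was lost without not-injected replicate 1, 2 or 3 or TFEB-injected replicate 2 (adjusted p = 0.103, 0.0990, 0.0701 and 0.106), and over all settings the adjusted p ran from 3.19e-04 to 0.114; TFEB or the vector acting by another route was not tested.

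The injected arrays varied more than the not-injected ones, with a median SD per gene of 0.08 against 0.06, a ratio of 1.27 over all genes, 1.53 over called genes, 1.21 over genes not called and 0.95 over the 3098 genes with the lowest levels. For array noise or labelling, the ratio over the 45 non-mouse control probe sets was 1.04, a value set in advance as arguing against it. That limit proved unsuited, because the 18 bio and cre controls gave 1.63 and the 24 dap, lys, phe and thr controls 0.71, so noise cannot be told apart from differences between mice. A different strength of one response may contribute, since 29.2% of the squared deviations of called genes lay along the mean response of the other 2 arrays, short of the limits set for either answer. The slopes on that response were 0.79, 1.00 and 1.18 for TFEB-injected replicates 1, 2 and 3.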
